A study of Arabidopsis thaliana with 22 samples.

How the data were processed

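Gene expression was measured in roots of Arabidopsis thaliana Col-0, taken from plants that were 10 days old per the labels. The 22 RNA samples were each put on 1 array. Plants had been moved to agar medium with either 0 or 1500 uM sulfate and were sampled 2, 4, 8, 12 and 24 h later, and a further group, labelled 0 h, was not transferred. These make 11 groups with 2 arrays each, which the labels distinguish by the letters A and B. Nothing in the sources used here says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

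The deposited values are probe set signals on a linear intensity scale, made with MAS5 per the submitters' processing notes. The version of MAS5 and the scaling target are not given in the sources used here. The mean signal after trimming 2% of the probe sets at each end was 100.01 on every array, so the authors' values were already scaled between arrays and no further normalization was applied. The pooled median signal was 43.9. Arrays carry no counting depth; the number of arrays limits the precision.

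Of 22810 probe sets, 64 array controls were left out of the tests. The other 22746 were put on a log2(signal + 11) scale, where 11 is 0.25 of the pooled median, rounded. All fold changes are on that scale, which understates the change of dim probe sets. Probe sets with a mean at or above the 40th percentile, which corresponds to a signal of about 27, were kept, and 13648 remained. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). All 22 arrays entered 1 fit of the 11 groups, since 2 arrays per group alone give a poor estimate of the spread, with 11 residual and 5.61 prior degrees of freedom. The median standard error of a log2 difference was 0.172 at a single time and 0.077 for the mean over the 5 times. P-values were adjusted by the Benjamini-Hochberg method over the probe sets kept, with a threshold of 0.05.

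Gene names came from the platform annotation, which lists 14016 of these probe sets. It gives 1 gene for 13513 of them and several for 503, and 8730 are unnamed here, which does not mean that they detect no gene. Among the 13648 probe sets kept, 7333 had 1 gene, 287 several and 6028 none listed. Symbols were updated through the RefSeq gene table of assembly TAIR10.1, which matched 13436 of the 13513 genes and left 77 under the annotation's name. A probe set that lists several genes was never used to name a gene. No genome build is stated with the values, so no coordinates are given.

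The comparisons were sulfate-free minus sulfate-replete medium at each of the 5 times, the mean of these differences, a moderated F-test that the 5 differences are equal together with the 24 h difference minus the 2 h difference, and replete medium at each time minus the untreated 0 h roots. The tests, the rule for named genes and 23 gene lists were fixed before the data were examined. By that rule the text names, for each time and for the mean over times, the 10 largest rises and 10 largest falls past the threshold on probe sets with 1 gene whose arrays (for the mean, whose group means at all 5 times) do not overlap between media. It also names the 10 smallest p-values of the F-test, the 5 largest rises and 5 largest falls against untreated roots, all measured members of the 5 sulfur lists, and example members of other lists. The 23 lists had 323 entries, of which only 39 lay on named probe sets, 6 lists had none, and 3 lists kept at least 3 tested members. For that reason 17 further lists were drawn up from the annotated genes after the annotation had been seen and before any difference between arrays was computed; they are called added lists. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over 120 list and contrast pairs for the media, and again with a correlation estimated from the residuals.

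The letters A and B appear in every group. Whether they pair the arrays was decided from the deviations of arrays from their group means, before any calls were compared. Over probe sets, the A minus B differences of both media correlated at the same time with r of 0.631 at 2 h, 0.607 at 4 h, 0.225 at 8 h, 0.316 at 12 h and 0.429 at 24 h. Those of replete and untreated roots correlated with r between 0.238 and 0.496. Over all 55 pairs of groups, r lay between 0.028 and 0.644 with a median of 0.316, and 54 pairs were over 0.1. The arrays were therefore taken to be paired by letter. The fit described above has no block, as fixed beforehand, and so ignores this pairing. The named genes, the main list tests, the simulation and the random splits use that fit. A further fit took the letter as 1 factor over all arrays, and another took arrays of the same time and letter as a block. Values from both are given for the main results whose call or count they change. Counts of list members against untreated roots come from the fit without a block.

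The fit was tested on simulated data, in 5 sets of 13648 probe sets with 200 changed probe sets each. In the 24 h comparison it recovered 87.8% of changes of log2 size 1 and 99.8% of those of size 2, with 46 false calls over the 5 sets. For the mean over the 5 times it recovered 99.6% and 100% with 43 false calls. The F-test recovered 97.2% of changes of log2 size 2 present at 24 h alone, with 37 false calls. The simulated arrays had normal spread, independent between arrays and probe sets, and no difference between letters. The real arrays differ by letter, so these rates need not hold for them.

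Alternatives were other pseudocounts, other filters, quantile normalization, median centring, other variance models, both blocks, fits on fewer arrays, other set tests and leaving out each array in turn. The closing section gives their effect.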

Results

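Transcript levels in roots of 10-day-old Arabidopsis plants were followed for 24 h after transfer to agar without sulfate or with 1500 uM sulfate, to ask how roots respond to sulfate limitation. There were 2 arrays for each medium at 2, 4, 8, 12 and 24 h, and 2 arrays of roots that were not transferred. The median signal of the arrays lay between 42.45 and 46.17. Within groups the 2 arrays correlated with r between 0.96 and 0.983, and the SD of their log2 difference lay between 0.24 and 0.37. Values below are mean MAS5 signals ± SD with n = 2 per group, and log2 differences with their standard error (SE) from limma. Between media, a rise or fall means a higher or lower level without sulfate than on replete medium, not a change from untreated roots.

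After 24 h without sulfate, BCAT4, the aminotransferase at the entry of methionine chain elongation for aliphatic glucosinolates, fell from 1385 ± 129 to 206 ± 7 (SD, n = 2), a log2 difference of -2.68 (SE 0.17, adjusted p = 1.49e-07) or 6.41-fold. AT4G31330, a gene of unknown function, rose 6.03-fold, from 53.9 ± 5.53 to 383 ± 76.9 (log2 2.59, SE 0.24, adjusted p = 9.34e-06). AT1G04770, listed beforehand as the sulfur-limitation marker SDI2, rose 2.47-fold, from 173 ± 49.8 to 440 ± 100 (log2 1.3, SE 0.22, adjusted p = 0.00682). AT3G56200, a putative amino acid transporter, rose 2.53-fold to 404 ± 5.61, and AT1G75280, an isoflavone reductase homologue, rose 2.58-fold to 1119 ± 83.3. AT5G40670, a homologue of the cystine exporter cystinosin, rose 2.04-fold (adjusted p = 0.00149), and the kelch-repeat F-box gene AT3G27150 rose 2.29-fold (adjusted p = 0.0287).

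The smaller rises at 24 h were those of the flavin monooxygenase gene AT1G12200 (symbol FMO; log2 0.77, adjusted p = 0.0134) and the glutathione transferase GSTU27 (log2 0.70, adjusted p = 0.047). Among the falls, AT2G25450, a dioxygenase that hydroxylates an alkenyl glucosinolate, went from 788 ± 78.9 to 277 ± 4.54 (log2 -1.47, SE 0.16, adjusted p = 4.91e-05). The glucosinolate glucosyltransferase genes AT2G31790 (UGT74C1) and UGT74B1 fell too (log2 -1.59 and -0.91, adjusted p = 0.00306 and 0.00861). The transporter gene AT3G45700 of the nitrate and peptide transporter family fell by 1.22 on the log2 scale (adjusted p = 0.00138). AT1G21440 (-1.36) and AT3G14280 (-1.02) fell as well. AT4G25835, AT3G50620 and AT5G44720, the last of the molybdenum cofactor sulfurase family, fell with log2 differences of -0.85, -0.72 and -0.58. The largest rises of all belonged to 2 probe sets that are unnamed here, with log2 differences of 4.51 (SE 0.30) and 4.42 (SE 0.55), and the largest unnamed falls were -2.51 (SE 0.12) and -1.99 (SE 0.20).

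In total 22 probe sets rose and 27 fell at 24 h, of which 8 and 10 name a gene. With the letter as a factor 33 rose and 41 fell, and with the arrays of the same time and letter as a block 41 rose and 60 fell. All 49 calls were also made in both blocked fits. Without the replete 24 h array B the count was 27, and without the sulfate-free 24 h array A it was 30.

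BGLU28, a beta-glucosidase gene induced by sulfur shortage and the other measured marker of that list, lay below the filter because its signal was low in most groups. Tested without the filter, it rose at 24 h (log2 4.29, SE 0.26, adjusted p = 4.47e-07), from 8.03 ± 2.57 to 362 ± 42.6 (SD, n = 2), and at 12 h to 105 ± 8.86 (adjusted p = 2.17e-04). The replete signal is not shown to be above background (25th percentiles at 24 h 9.754 and 12.54), so the sizes of these rises depend on the pseudocount. At 8 h its signal was 36.5 ± 8.65 without sulfate and 12.8 ± 1.44 with it (adjusted p = 0.297).

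**Figure D1:**
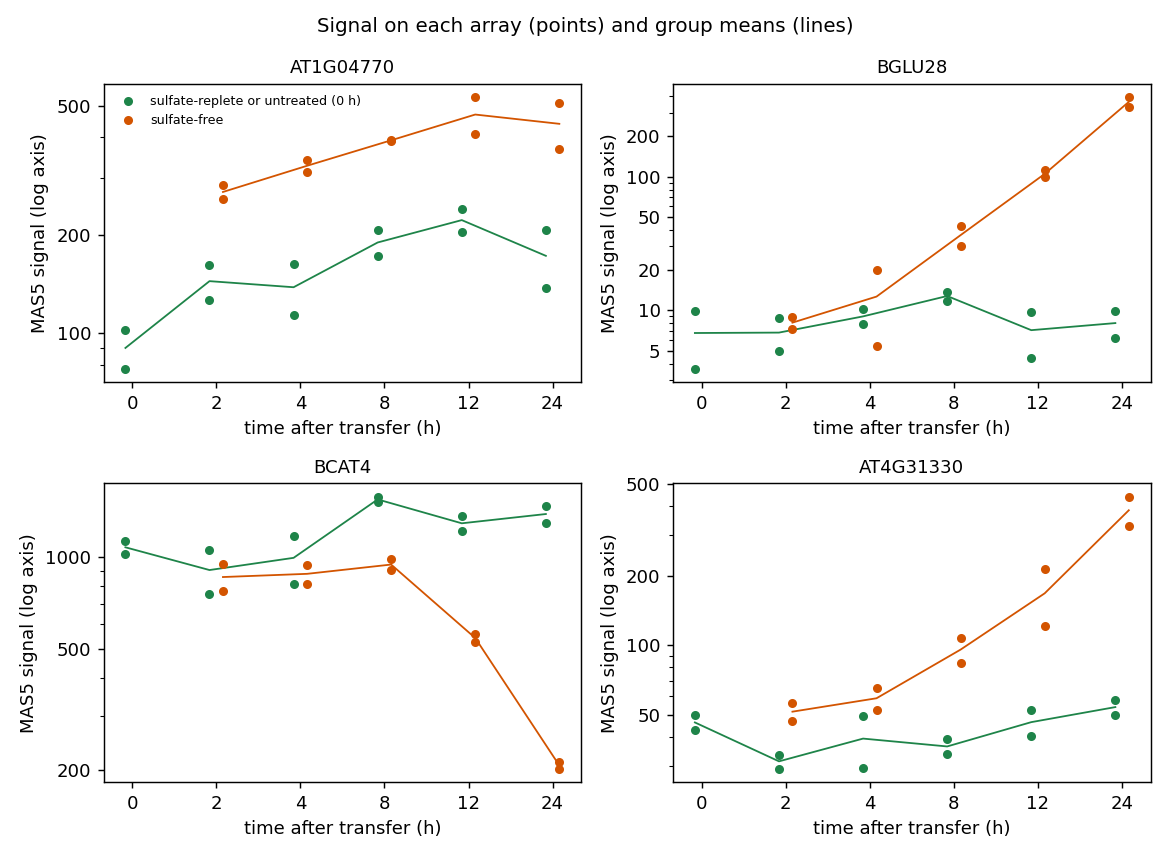
MAS5 signal (log axis) of AT1G04770, BGLU28, BCAT4 and AT4G31330 on each array (points) and as group means (lines) against time after transfer in h, with the times spaced equally. Both sulfate-free arrays of BCAT4 lie below both replete arrays at 24 h (206 against 1385 on average), and those of BGLU28 lie above them (362 against 8.03).

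At 12 h, 4 named genes passed the test, and all 4 also passed at 24 h. BCAT4 fell from 1291 ± 104 to 542 ± 23.7 (log2 -1.24, SE 0.17, adjusted p = 0.00552, n = 2). AT4G31330 rose 3.02-fold (adjusted p = 0.00642), AT1G75280 1.61-fold (adjusted p = 0.037) and AT3G56200 1.67-fold (adjusted p = 0.0428). With the unnamed probe sets, 13 rose and 4 fell, against 23 and 21 with the letter as a factor and 27 and 35 with the block of time and letter. The count of 17 fell to 2 without the sulfate-free array B, to 7 without the replete array A and to 2 without the replete array B of 12 h. Without the sulfate-free array A of 12 h, 4 rose and 10 fell, and only 7 of the 17 calls were among them.

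Before 12 h the only call in limma was the rise at 8 h (log2 3.13, SE 0.30, adjusted p = 1.76e-04) of the unnamed probe set that also had the largest rise at 24 h. No probe set passed at 2 or 4 h, where 262 and 329 had an unadjusted p under 0.05, which is 1.92% and 2.41% of the probe sets. These shares cannot be read against a chance share of 5%. The unblocked fit counts the difference between letters, which both media share, as spread, and so its p-values are too large. Fits on the 4 arrays of a time alone gave 0, 0 and 1 calls at 2, 4 and 8 h. The letter factor gave 0, 1 and 3, and the block of time and letter gave 2, 8 and 17. AT1G04770 was among the early calls with the block of time and letter, and not among those with the letter factor. Its signal at 2 h was 272 ± 19.9 without sulfate and 145 ± 25.3 with it, a log2 difference of 0.87 (SE 0.22), and its adjusted p was 1 without a block, 0.0182 with the block of time and letter and 0.933 with the letter factor. At 4, 8 and 12 h its differences were 1.2, 1.01 and 1.03, with adjusted p = 0.288, 0.429 and 0.127 unblocked and 8.1e-04, 0.00219 and 5.69e-04 with the block of time and letter. With the letter factor the adjusted p at 12 h was 0.0375, and at 4 and 8 h it was 0.0895 and 0.0918. For AT3G56200 the block gave adjusted p = 0.0495 at 4 h and 0.00565 at 8 h (letter factor 0.213 and 0.0337), and for BCAT4 it gave 0.0125 at 8 h (letter factor 0.0918). Without the replete 8 h array B the count at 8 h was 100, and without the sulfate-free 4 h array A the count at 4 h was 1.

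**Figure D2:**
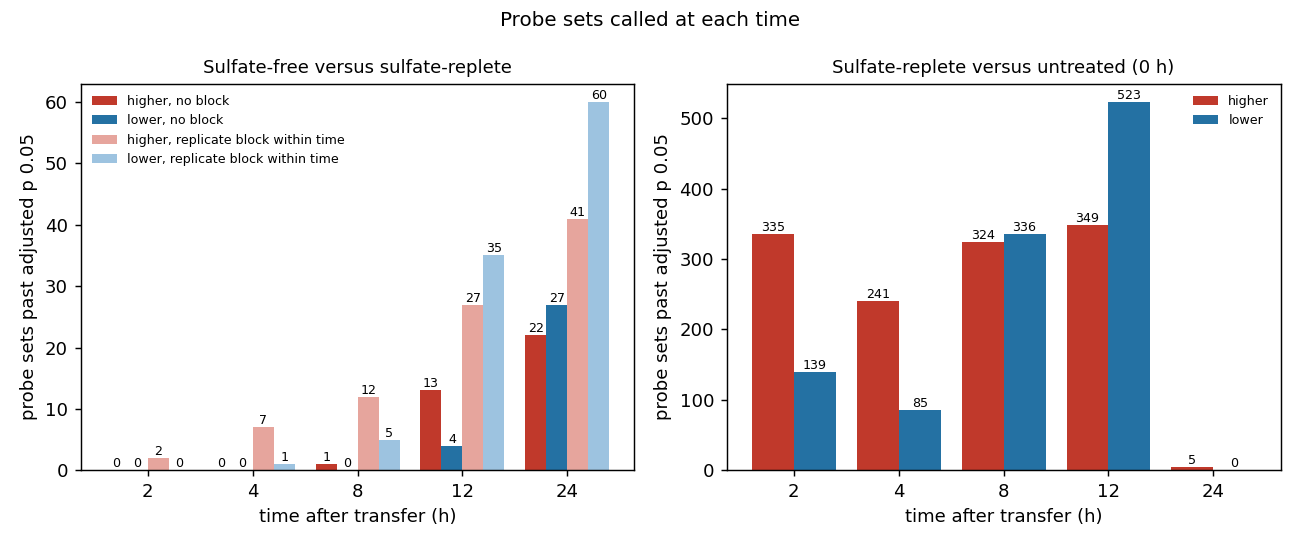
Number of probe sets called by limma at each time after transfer (h, equally spaced), for sulfate-free against replete medium (pale bars with the block of time and letter) and for replete medium against untreated roots. Unblocked calls between media rise to 49 at 24 h, while those against untreated roots are most at 12 h (872) and fewest at 24 h (5).

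Over the 5 times together, sulfate-free roots had more transcript of AT4G31330 (log2 1.28, SE 0.11, adjusted p = 2.52e-06), AT1G04770 (1.08, SE 0.10, adjusted p = 5.89e-06) and AT3G56200 (0.79, SE 0.06, adjusted p = 1.54e-06), from 10 arrays of each medium. GTR1, which encodes a glucosinolate importer, rose by 0.35 (SE 0.07, adjusted p = 0.0194), and the berberine bridge enzyme-like gene AT4G20820 rose by 0.39. AT3G27150, AT5G40670, AT1G75280, GSTU27 and FMO, all called at 24 h, rose by 0.65, 0.57, 0.54, 0.34 and 0.33. BCAT4 was lower, with a mean log2 difference of -0.97 (SE 0.08, adjusted p = 1.77e-06), followed by GSTU20, a glutathione transferase tied to aliphatic glucosinolate synthesis (-0.78, SE 0.15, adjusted p = 0.0225), and AT2G31790 (-0.66). AT1G61740, of the TauE and SafE sulfite exporter family, fell by 0.43 on the log2 scale (SE 0.06, adjusted p = 6.37e-04). The rule names at most 10 falls, each with the same sign at all 5 times. The further falls it names were those of AT3G14280 (-0.54), AT5G01740 (-0.53), AT3G45700 (-0.49), AT4G25835 (-0.44), AT5G60760 (-0.43) and AT3G50620 (-0.31). That of AT5G60760 is relative to replete medium only. Compared with untreated roots, it was higher without sulfate at 4 and 8 h (log2 1.54 and 0.78, limma adjusted p = 1.79e-05 and 0.00652). At 24 h it was not called against them (-0.48, adjusted p = 0.249). Among probe sets unnamed here, the largest mean differences were 2.87 and 2.33 for rises and -0.90 and -0.71 for falls.

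The mean over times called 33 rises and 32 falls, 65 in all, of which 11 and 14 name a gene. The letter factor gave 66 rises and 77 falls and the block of time and letter 139 and 145, and both held all 65. GSTU20 at 24 h is a case of a call that the blocks add: its difference of -1.59 (SE 0.34) had adjusted p = 0.0622 unblocked, 3.8e-07 with the block of time and letter and 4.35e-05 with the letter factor. Over the times 2 to 12 h alone, a setting chosen after the data were seen, 22 probe sets rose and 9 fell. A fit on the 20 arrays after transfer alone gave 31 rises and 14 falls.

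**Figure D3:**
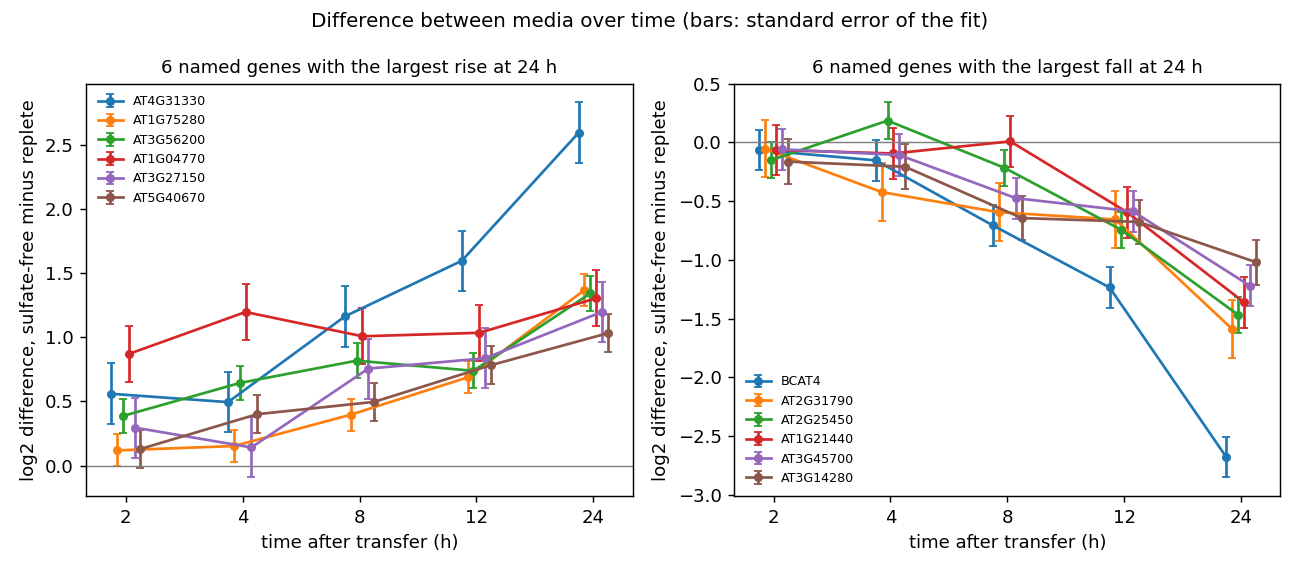
Log2 difference between sulfate-free and replete medium (y axis, ± SE from limma, n = 2 arrays per medium) against time after transfer in h, equally spaced, for named genes. BCAT4 goes from -0.06 at 2 h to -2.68 at 24 h, AT4G31330 from 0.56 to 2.59, and AT1G04770 from 0.87 to 1.3.

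The difference between media itself changed with time for 3 named genes among the probe sets kept. Tested without the filter, BGLU28 passed the F-test too (adjusted p = 2.08e-04). Its 24 h difference exceeded that at 2 h by 4.19 (SE 0.37, limma adjusted p = 8.12e-05), a size that depends on the pseudocount. The F-test that the 5 differences are equal was passed by BCAT4 (adjusted p = 2.29e-04), AT2G25450 (0.0212) and AT1G75280 (0.0212). BCAT4 differed between media by -0.06, -0.15, -0.71, -1.24 and -2.68 at 2, 4, 8, 12 and 24 h, and AT1G75280 by 0.12, 0.15, 0.40, 0.69 and 1.37. For AT4G31330 the 24 h difference exceeded that at 2 h by 2.03 (SE 0.33, adjusted p = 0.0137), while its F-test gave adjusted p = 0.0537. For AT1G04770, by contrast, the differences at the 5 times lay between 0.87 and 1.3. The F-test called 11 probe sets, against 21 with the letter factor and 32 with the block of time and letter, and the difference between 24 h and 2 h called 15, against 34 and 42. Leaving out 1 array moved the count of 11 to between 4 and 28, with 4 or 5 calls without any of the 4 arrays of 24 h and 28 without the replete 8 h array B, and the count of 15 to 9 without the replete 2 h array A.

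Genes of aliphatic glucosinolate synthesis were lower as a group without sulfate. Of the 24 genes listed, 4 could be tested: BCAT4, UGT74B1, AT2G31790 and GSTU20. At 24 h 3 of them fell, 4 adjusted over the list alone, with a median log2 difference of -1.59 (camera adjusted p = 1.81e-24; adjusted p = 0.00665 with an estimated correlation). Over the 5 times 3 fell, again 4 adjusted over the list alone (adjusted p = 1.78e-15; 0.0118 with an estimated correlation). At 12 h 1 fell, 3 adjusted over the list alone (adjusted p = 3.36e-08; adjusted p = 0.0843 with an estimated correlation). The list's adjusted p was 2.14e-04 at 8 h and 0.0496 at 4 h, and 0.376 and 0.751 with an estimated correlation. UGT74B1, which acts in indole glucosinolate synthesis too, was the single tested member of that list. Its mean difference over the times was -0.30 (SE 0.07), with adjusted p = 0.0931 unblocked, 0.00425 with the block of time and letter and 0.0101 with the letter factor.

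The added list of glucosinolate pathway and endoplasmic reticulum body genes had 14 tested members, which include these 4. BGLU28 is on this list too but lay below the filter and was not tested with it. In limma without the filter BGLU28 rose at 24 h (log2 4.29, SE 0.26, adjusted p = 4.47e-07), against the direction of the list. At 24 h 3 fell, and over the 5 times 3 fell while GTR1 rose (camera adjusted p = 1.46e-09 and 9.39e-09; 0.00671 and 0.00685 with an estimated correlation). Its adjusted p at 12 h was 4.71e-05 (0.0377 with an estimated correlation, 0.0988 with rank-based camera) and at 8 h 0.00331 (0.13 with an estimated correlation, 0.0305 rank-based). With the filter off, BGLU28 counts among the list's members, and the list was not called at 8 or 12 h. At 24 h none of the 14 tested members outside glucosinolate synthesis passed without a block. PYK10, the main beta-glucosidase of endoplasmic reticulum bodies, differed by 0.04 (SE 0.18) and the transcription factor gene MYC3 by -0.16 (SE 0.13). At 2, 4, 8 and 12 h PYK10 differed by -0.42, 0.26, -0.15 and -0.66, with no call over all probe sets. Adjusted over the list alone, 6 of the 14 fell and 1 rose at 12 h, and 5 fell and 1 rose at 24 h. GTR1 at 24 h differed by 0.60 (SE 0.15), with adjusted p = 0.195 unblocked, 0.015 with the block of time and letter and 0.0269 with the letter factor.

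**Figure D4:**
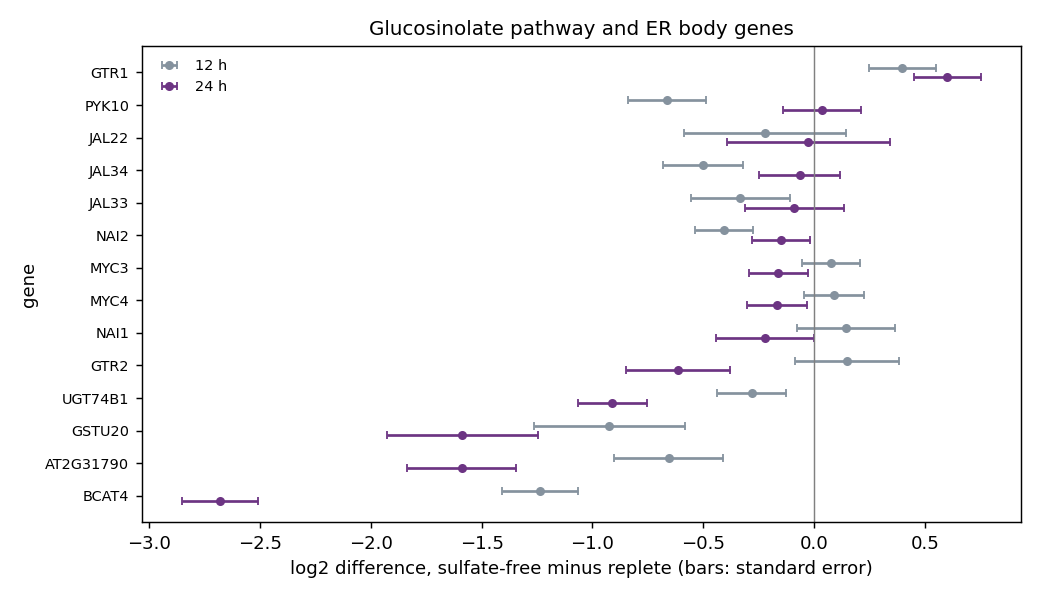
Log2 difference between sulfate-free and replete medium (± SE from limma, n = 2 arrays per medium) at 12 h (grey) and 24 h (purple) for glucosinolate pathway and endoplasmic reticulum body genes. The 4 tested genes of aliphatic synthesis all lie below 0 at 24 h, from -2.68 for BCAT4 to -0.91 for UGT74B1, while GTR1 lies at 0.60.

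For sulfate uptake and assimilation the named probe sets covered few genes. None of the listed sulfate transporter or cysteine synthesis genes was on a named probe set, and the single tested gene of glutathione synthesis and breakdown, AT1G44790, had a difference of -0.31 (SE 0.17, adjusted p = 1) at 24 h. In sulfate activation and reduction, 3 members were tested and 0 passed by limma over all probe sets, but adjusted over the list alone 1 rose and 1 fell at 24 h. APS3, an ATP sulfurylase gene, had a log2 difference of 0.79 (SE 0.25, adjusted p = 0.7), and APS4, another, had -0.52 (SE 0.13, adjusted p = 0.217). With the block of time and letter these became 0.00738 and 0.0255, and with the letter factor 0.0179 and 0.0455. The sulfite reductase gene SIR differed by -0.24 (SE 0.21, adjusted p = 1). As a set the 3 genes had adjusted p = 0.566 (0.94 with an estimated correlation).

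Methionine and S-adenosylmethionine genes had 4 tested members, of which 0 passed over all probe sets and 1, CBL (-0.39, SE 0.13), fell adjusted over the list alone at 24 h (set adjusted p = 0.772). Of 24 tested genes on the added sulfur metabolism list AT1G04770 alone was called without a block, rising at 24 h and over the 5 times (set adjusted p = 0.771 and 0.554). APS3 and APS4, called at 24 h in both blocked fits, are members of this list too. So is BGLU28, which lay below the filter and was not among the tested members. Of 11 glutathione transferase genes GSTU27 rose and 0 fell at 24 h in limma without a block. With both blocks GSTU20 was lower than on replete medium at 24 h (-1.59, adjusted p = 3.8e-07 and 4.35e-05). Over the 5 times GSTU27 rose and GSTU20 was lower than on replete medium. Of 25 UDP-glycosyltransferase genes UGT74B1 alone fell at 24 h without a block; AT2G31790 (UGT74C1), which fell as well, is not on that list. The other added lists, on expansins, auxin, autophagy, calcium and jasmonate, cold, branched-chain amino acids, iron, dividing cells, sugar transport, heat and endoplasmic reticulum stress, had adjusted p between 0.499 and 0.985 at 24 h.

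Markers of other root and shoot cell types showed no call between media by limma. At 24 h the green tissue genes LHCB4.1 and RCA differed by 0.05 (SE 0.26) and -0.35 (SE 0.25), the root hair genes EXPA7 and EXPA18 by -0.08 (SE 0.23) and -0.02 (SE 0.31), and AUR1 of dividing cells by 0.19 (SE 0.20). No listed endodermis or vascular marker was on a named probe set. The added list of nuclear photosynthesis genes had adjusted p = 0.0071 at 12 h, with 0 of 10 members called (adjusted p = 0.616 with an estimated correlation). The 57 tested chloroplast-encoded transcripts had a median difference of -0.14 at 24 h and 0 calls, with camera adjusted p = 0.0845 unblocked and 0.00349 with the letter factor. That factor also gave adjusted p = 0.0415 for their lower level at 4 h, 0.0478 for their higher level at 8 h, and 0.00843 for a higher level of 10 autophagy genes at 2 h. These 4 calls were made at the preset correlation, and no estimated correlation was run with the letter factor. Unblocked, each of the 4 had camera adjusted p = 0.94 with an estimated correlation. The unblocked residuals still hold the difference between letters, so that value cannot tell what the calls with the letter factor rest on. On the control genes, the mean log2 ratio of 3' to 5' signal was 0.26 in sulfate-free and 0.23 in replete roots at 24 h. Of all arrays, the ratio was highest, 0.60, on the replete 8 h array A and lowest, 0.08, on the replete 8 h array B. Fits without that array B therefore compare 8 h with array A alone.

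From 2 to 12 h, roots on replete medium differed from untreated roots in many more transcripts than the media differed from each other. At 2 h the largest named rises over untreated roots were those of AT5G62360, a pectin methylesterase and invertase inhibitor (from 3.91 ± 1.63 to 251 ± 120; log2 4.06, SE 0.41, adjusted p = 1.07e-05, n = 2) and AT2G38240, a jasmonate oxidase gene (log2 3.78). They were followed by AT5G52050, an efflux carrier gene (3.70), AT4G22610 (3.63) and AT4G18280 (2.98). The untreated signals of AT5G62360, AT2G38240 (9.40) and AT5G52050 (3.13) lie below the 25th percentiles of the untreated arrays (10.57 and 10.72) and are not shown to be above background, so the sizes and ranks of these rises depend on the pseudocount. The falls were those of AT2G41810 (log2 -1.92), AT5G57785 (-1.82), AT3G45160 (-1.3), the osmotin gene OSM34 (-1.23) and AT3G32040 (-1.15). At 4 h AT4G22610, AT5G62360 and AT5G52050 were still higher (log2 3.09, 2.61 and 2.49), with AT4G30650 (2.46) and the cell wall enzyme gene XTH20 (2.37). The falls at 4 h were those of AT1G33055 (-1.96), AT1G78990 (-1.92), the S-adenosylmethionine decarboxylase family gene AT5G15950 (-1.37), AT1G64590 (-1.3) and AT5G57785 (-1.26).

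At 8 h XTH20 was 9.31-fold higher than in untreated roots (609 ± 75.9 against 55.8 ± 10.9; log2 3.22, SE 0.38, adjusted p = 6.94e-05, n = 2), and PDC2, a pyruvate decarboxylase of ethanol fermentation, was 5.49-fold higher. AT4G30650, AT5G62360 and AT1G56300 rose by 2.68, 2.56 and 2.37 on the log2 scale. The protein phosphatase gene AT3G16800 was lower at 8 and 12 h (log2 -2.34 and -3.02), from 427 ± 22.0 to 76.2 ± 14.4 and 43.0 ± 2.03. So were AT1G33055 (-2.73 and -3.35) and AT3G13040 (-1.97 and -1.94). AT5G15950 (-1.94) and bZIP58 (-1.71) fell at 8 h, and AT4G27450 (-2.03) and AT3G15450 (-1.98) at 12 h. At 12 h XTH20, AT4G30650 and PDC2 remained higher (2.64, 2.41 and 2.37), and 2 glucosyltransferase genes, UGT84A1 and AT2G22590, rose by 2.58 and 2.39. GI, the tested circadian clock gene, rose by 0.65, 1.06 and 0.89 at 2, 4 and 8 h (adjusted p = 0.0487, 0.00204 and 0.00595) and had -0.46 (adjusted p = 0.128) at 12 h. At 24 h the only named calls were AT5G38020, a methyltransferase gene (2.54-fold, adjusted p = 8.83e-04), and AT3G59340 (2.11-fold, adjusted p = 0.00692).

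Counts against untreated roots were 335 rises and 139 falls at 2 h, 241 and 85 at 4 h, 324 and 336 at 8 h, 349 and 523 at 12 h, and 5 and 0 at 24 h, where 888 had an unadjusted p under 0.05. With the letter factor the rises and falls were 566 and 352, 479 and 270, 730 and 856, 977 and 1225, and 60 and 23. All 5 comparisons use the same 2 untreated arrays, and without untreated array A the counts were 193, 101, 178, 208 and 3. The balance of rises and falls also rests on single arrays: without the replete 4 h array A it was 133 and 102 at 4 h, and without the replete 8 h array B it was 229 and 413 at 8 h. Transfer, age and time of day change together in them. The 24 h count was 0 without the replete 24 h array A, and the 8 h count was 273 without the replete 8 h array A, the array with the highest 3' to 5' ratio.

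Among the lists, UDP-glycosyltransferase genes were higher than in untreated roots at 2 h, with 7 rises and 1 fall among 25, and at 4 h, with 5 rises (adjusted p = 0.00313 at both; adjusted p = 0.0658 with an estimated correlation). Nuclear photosynthesis genes were lower at 12 h, with 5 falls among 10 and a median of -0.80 (adjusted p = 0.00112), and at 2 h (0.0325; 0.421 and 0.691 with an estimated correlation). Aliphatic glucosinolate genes were higher at 8 h (adjusted p = 0.0215) and 24 h (0.00124), with no member called by limma without a block and adjusted p = 0.597 and 0.421 with an estimated correlation. With the letter factor GSTU20 was called at both times, with values given further below. Calcium, jasmonate and defence genes were higher at 2 h (adjusted p = 0.00385, 1 of 12 rose; adjusted p = 0.485 with an estimated correlation). Set calls with at most 2 members called were made for the glucosinolate pathway at 4, 8 and 24 h (higher; adjusted p = 0.0197, 0.0131 and 0.0215), autophagy at 2 h (lower; 0.0325), chloroplast-encoded transcripts at 4 h (higher; 0.0325), and at 24 h cold and dehydration (lower; 0.0215) and expansins and xyloglucan transferases (higher; 0.0325). With an estimated correlation these had adjusted p = 0.407 at all 3 times for the glucosinolate pathway, and 0.861, 0.942, 0.636 and 0.597 for the others in that order.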

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

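All values tested here for the growth of the sulfate effect were chosen after that growth was seen, except the test for selection of genes, and the last of the 4 random-split tests was chosen after the result was seen.

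The difference between media was not the same at all times: the F-test called 11 probe sets, and 15 differed between 24 h and 2 h. The 24 h difference minus the 2 h difference was -2.617 for BCAT4, -1.316 for AT2G25450 and 1.249 for AT1G75280 on the log2 scale. Lower precision at 2 h could hide early effects, but the spread of A minus B at 2 h was 1.05 times that at 24 h. For a smaller share of green tissue, the chloroplast-encoded transcripts had a median of -0.143 at 24 h against 0.577 for the smallest called change. As a set they did not shift by that size. Of these 57 transcripts 33 were higher in B arrays, and how well they follow the share of green tissue was not tested, so that share stays open. Selection of genes at 24 h would not explain that 17 of the 17 probe sets called at 12 h changed more at 24 h than at 2 h, with medians in the called direction of 0.26, 0.46, 0.82, 1.24 and 1.81 over the 5 times. What makes the difference grow was not tested beyond these 3 explanations, and the time at which it starts was not settled, since AT1G04770 at 2 h is called with the block of time and letter (adjusted p = 0.0182) and not with the letter factor (0.933).

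Random splits of the arrays tested whether chance could give the mean over the 5 times. Within each time, 4 of 100 splits, the real one included, gave at least 65 calls, and the other 3 gave 627, 481 and 147. A split by letter at all 5 times gave 3977 calls, which points to the letters as a structure of the samples. These 3 splits part the arrays by letter one way at 3, 3 and 2 more times than the other way. Whether the letters explain their counts was not tested. With blocks the real split gives 143 or 284 calls. Among splits that part every pair of same-lettered arrays, 1 of 100, the real one, had that many calls, and the highest other count was 42. For the aliphatic glucosinolate list, 2 of 100 splits within times, the real one included, had a set test p as small as the real one (2.96e-17; lowest other 5.47e-19), and so did 5 of 100 splits that part every pair, the real one again included (lowest other 5.91e-19). The 4 others of these keep 8, 7, 6 and 6 of the 10 arrays on the real side. For the p-value of that list chance was not excluded by the last test, and no split was run with the estimated correlation of 0.643.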

How the results depend on the processing

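All settings were chosen beforehand except the mean over 2, 4, 8 and 12 h only. Media counts at 2, 4, 8, 12 and 24 h and for the mean were 0, 0, 1, 17, 49 and 65, and the 2690 alternative values of named genes were kept in 2490 cases, weaker in 200 and reversed in 0. Most of these values leave out 1 array. With only the 4 arrays of a time 14 of 22 values at single times were weaker, and of 20 values for the mean 11 were weaker over 2, 4, 8 and 12 h only. In the fit on the 20 arrays after transfer, which also takes the effect of the medium as equal at all times, 7 of these 20 were weaker (31 rises, 14 falls). The letter factor gave 1 at 4 h, 3 at 8 h, 44 at 12 h, 74 at 24 h, 143 for the mean, 34 for 24 h minus 2 h, 21 for the F-test, and 918, 749, 1586, 2202 and 83 against untreated roots at 2, 4, 8, 12 and 24 h. The block within each time gave 2, 8, 17, 62 and 101 at the 5 times, 284 for the mean, 42 for 24 h minus 2 h and 32 for the F-test. Pseudocount 1 gave 1 at 4 h, a pseudocount equal to the pooled median gave 4 at 8 h, no filter gave 7 and the 60th percentile gave 0 at 8 h, and the mean over 2, 4, 8 and 12 h only gave 31. Of 10 gene list calls, 5 remained with an estimated correlation and 5 with fry. No filter lost the glucosinolate pathway at 8 and 12 h and aliphatic synthesis at 4 h and added chloroplast transcripts at 4 h (0.00908) and 24 h (0.0494) and calcium and jasmonate at 12 h (0.00745). Rank-based camera lost the pathway at 12 h and added chloroplast transcripts at 24 h (0.015) and nuclear photosynthesis for the mean (0.0305), quantile normalization added sulfur metabolism at 2 h (0.0428), and pseudocount 1 lost aliphatic synthesis at 4 h. Leaving out 1 array gave 0 to 1 at 4 h (1 without S0_4H A), 1 to 100 at 8 h (100 without S1500_8H B; 2 without S0_4H A, S0_4H B, S1500_0H A or S1500_0H B), 2 to 16 at 12 h (2 without S0_12H B or S1500_12H B, 7 without S1500_12H A), 27 to 53 at 24 h (27 without S1500_24H B, 30 without S0_24H A), 53 to 83 for the mean, 9 to 19 for 24 h minus 2 h (9 without S1500_2H A) and 4 to 28 for the F-test (4 without S0_24H A or S1500_24H B, 5 without S0_24H B or S1500_24H A, 28 without S1500_8H B). Against untreated roots, it gave 193 to 505 at 2 h (193 and 282 without S1500_0H A and B, 235 and 231 without S1500_2H A and B), 101 to 352 at 4 h (101 and 212 without S1500_0H A and B, 192 without S1500_4H B), 178 to 779 at 8 h (178 and 421 without S1500_0H A and B, 273 without S1500_8H A), 208 to 1066 at 12 h (208 and 539 without S1500_0H A and B, 336 and 295 without S1500_12H A and B) and 0 to 6 at 24 h (3 without S1500_0H A, S1500_0H B or S1500_24H B, 0 without S1500_24H A). Why single arrays move these counts was not tested.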

Other observations

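Of the tests on the letters and on the counts against untreated roots, those of another phase of the course, of lower precision at 24 h and of a response that is strongest first were chosen after the result was seen; genes and lists of the letter difference were also picked after their values were seen.

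Compared with untreated roots, AT1G04770 rose without sulfate by log2 1.49, 1.75, 2.00, 2.25 and 2.15 at 2, 4, 8, 12 and 24 h, and on replete medium it differed by 0.62, 0.55, 1.0, 1.21 and 0.85, so it rose there too at 8 and 12 h (adjusted p = 0.0129 and 0.0029). The median of the 4 aliphatic glucosinolate genes against untreated roots at 24 h was 0.53 on replete medium, with 0 of 4 called, and -0.72 on sulfate-free medium, with BCAT4 alone called (adjusted p = 5.04e-07). GSTU20 on replete medium differed by 0.89, 1.06 and 1.15 at 8, 12 and 24 h (adjusted p = 0.157, 0.0766 and 0.448 unblocked; 0.00418, 7.63e-04 and 0.00723 with the letter factor). Without sulfate GSTU20 differed from untreated roots by -0.24, -0.24, 0.14, 0.13 and -0.44 at 2, 4, 8, 12 and 24 h. None of these was called by limma without a block (adjusted p from 0.676 to 0.888). Sulfate-free roots had 595, 394, 605, 1152 and 91 probe sets that differed from untreated roots, and BCAT4 at 24 h was lower by a log2 difference of -2.32. BGLU28 went from a signal of 8.09 at 2 h to 12.7, 36.5, 105 and 362 without sulfate, while it stayed between 6.77 and 12.8 in all replete and untreated groups.

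In a fit with the letter, 4013 of 13648 probe sets differed between A and B arrays, 2040 higher and 1973 lower in B. The photosystem and ATP synthase genes psaA (log2 1.56), atpH (1.41), psbB (1.29) and psbD (1.1), all encoded in the chloroplast, and AT3G50590 (1.1) were higher in B, psaA in 11 of 11 groups. AT4G14060 (-0.90), AT3G47800 (-0.88) and AT2G33850 (-0.85) were lower. Of 57 chloroplast-encoded transcripts 33 were higher and 4 lower (median 0.27, adjusted p = 1.66e-09; adjusted p = 0.28 with an estimated correlation), while 10 nuclear photosynthesis genes had a median of -0.02. All 10 autophagy genes were lower in B (median -0.27, adjusted p = 1.99e-06; adjusted p = 0.28 with an estimated correlation). Of the 4 aliphatic glucosinolate genes 3 were higher in B (median 0.27, adjusted p = 0.00616; adjusted p = 0.148 with an estimated correlation).

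For this difference, RNA degradation in the arrays of 1 letter would raise the 3' to 5' ratio of the control genes for the same letter, and their mean was higher for A in 7 of 11 groups, short of what degradation would need. The actin ratio taken alone was higher for A in 11 of 11 groups (mean 0.47 against 0.11), but GAPDH was higher for A in 2 and ubiquitin in 5, so a difference in actin alone stays open. Intensity-dependent scaling could not account for it, as the median correlation between groups was 0.32 after quantile normalization. B arrays harvested at another phase of the course may share part of it, with r = 0.306 between B minus A and the course of replete roots from 2 to 12 h, which leaves this open. No explanation from biology was tested, because the sources used here do not say what the letters mean.

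Against untreated roots there were 474, 326, 660 and 872 calls at 2, 4, 8 and 12 h and 5 at 24 h. Lower precision at 24 h could not explain this, as the spread of A minus B there was 0.92 times that at the earlier times. A response to transfer that is strongest first and then fades could not by itself give an SD of the log2 differences that is larger by 0.07 at 12 h than at 2 h, but the SD was 0.33 at 2 h and 0.301 at 4 h and AT2G38240 went from log2 3.78 to 1.58, so a fading part mixed with a later change stays open. Time of day remains open: the change from 12 h to 24 h in sulfate-free roots correlated with r = -0.67 with that from 0 h to 12 h in replete roots, so changes present at 12 h tended to be reversed by 24 h. A slow response to transfer that ends by 24 h would give the same value, and no group here tells them apart.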
